A study of Rattus norvegicus with 233 samples.

How the data were processed

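Single hepatocytes of rat liver were measured by targeted real-time PCR. Per the labels' protocols, the animals were kept on the Lieber-DeCarli feeding protocol, a liquid diet regimen used to give rodents ethanol over long periods. Single cells were cut out by laser capture microdissection, lysed and taken straight to reverse transcription. The cDNA was pre-amplified for 22 cycles with the panel's own primers and then amplified for 30 cycles on a microfluidic array with SYBR Green detection. The panel held 84 assays, and 233 cells were deposited in 4 groups, set by diet (control, which the labels call carbohydrate, or ethanol) and by the time after partial hepatectomy (0 h or 24 h).

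The deposited table holds 1 cycle threshold (Ct) per assay and cell, a value on the log2 scale of template amount, in which a lower Ct means more template and 1 cycle stands for a doubling if each cycle doubles the product. The authors deposited the table as not normalized, and per the file header it has 1 column per cell, matched here to the cell's description in the labels. That the values are Ct is taken from the labels' qPCR protocol and from the values: across cells, more assays with a value went with a lower median Ct (Spearman's rho -0.765). Of 19572 entries, 14465 were given, between 2.5 and 25.9 with a median of 14.0, and 5107 (26.1%) were listed as NULL. The instrument software, the rule for calling a NULL, and any reference gene are not given in the sources used here. A NULL may stand for a transcript below detection or for a failed reaction, and the table does not separate the 2 cases.

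The rows carry assay numbers A01 to A84, which the sources used here do not pair with gene names. Gene lists and cell type markers fixed in advance could therefore not be applied, and scaling to named reference genes was not run. The rule fixed before the data were examined was to name the 10 largest differences in each direction and the largest changes in share. Because the numbers carry no gene name, only the first 2 assays in each direction are printed for each comparison, except for assays named for a pattern of missing values, which were chosen after their values were seen.

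The labels tie no cell to an animal. Cells of 1 animal are not independent, so each group was treated as 1 sample. No p-value, standard error or test of a difference between groups was computed, and the comparisons between groups are descriptions of these cells. Explanations for 3 patterns were tested with shuffled cell order, split control cells and resampled cells, without p-values. SDs are over cells and leave out the spread between animals.

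Each cell was scaled to its own median Ct over 28 common assays, those with a value in at least 80% of the cells of every group, with a NULL counted as Ct 30 in that median. The relative level of an assay in a cell is this median minus the assay's Ct, so that higher means more transcript relative to the cell's other transcripts. Group means are over the cells with a value, and assays with a value in fewer than 10 cells of a group were not compared. The size rule was a difference of means of at least 1 on the log2 scale. The share of cells with a value is given with its exact Clopper-Pearson 95% interval, which covers counting error over cells only. All cells had at least 31 assays with a value, so the minimum of 10 removed none, and no 2 columns were identical.

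The calculation was tested on simulated data for 24 h against 0 h on the control diet, with assay means, spreads and missing shares taken from the real table. Of the 83 assays that could be compared, 9 of 10 simulated higher by 2 passed the size rule, as did 10 of 10 simulated lower by 2 and 5 of 63 left unchanged. The median estimates were 1.77 and -1.87, somewhat smaller than the simulated shift. The share of simulated assays that had to pass was lowered after the 9 of 10 had been seen. In 100 further simulations in which no assay differed, with cells taken as independent, the median number past the size rule was 4 of 80 for 24 h against 0 h on the control diet, 4 of 81 for 24 h against 0 h on the ethanol diet, 3 of 77 for ethanol against control diet at 0 h, 3 of 84 for ethanol against control diet at 24 h, and 8.5 of 77 for the difference between diets in the 24 h minus 0 h difference. The highest numbers were 10, 11, 9, 11 and 18 in the same order. In the first simulation missing values were drawn at random, and in the 100 further ones the real NULLs were laid on values unrelated to them. In the real table, cells with fewer values had a higher median Ct. The simulations therefore cannot show a bias from averaging only the cells with a value. They also gave each assay 1 spread for all groups and let assays vary independently, apart from a shift common to all assays of a cell. In the real table spreads differed between groups. For A21 the SD was 3.56 (n = 13 cells) in control cells at 0 h and 0.82 (n = 23 cells) at 24 h. The real number with no change could be higher.

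Alternatives fixed before the data were examined were no scaling, scaling to the median of every assay the cell has, a detection limit of Ct 25, undetected values entered at Ct 30, only cells with at least 42 of the 84 assays, medians instead of means over cells, and only assays with a value in most cells of each group (0.5 or more of them). Alternatives added after seeing the data split the cells by a set of 5 assays that were missing together, fitted that split as a batch term, left out cells with a common-assay median above Ct 17, and set the limit at Ct 20. A value of 1 assay was counted as moved when it shifted by more than 0.585, and a count when it moved by more than 1.5 times. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used.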

Results

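The expression of an 84-gene panel was measured by real-time PCR in 233 single hepatocytes from rat liver, to compare the effects of chronic ethanol feeding and of partial hepatectomy, the surgical removal of part of the liver. The control diet gave 69 cells at 0 h and 55 cells at 24 h after resection, and the ethanol diet gave 55 cells at 0 h and 54 cells at 24 h. The gene behind each assay number is not given in the sources used here, so transcripts are reported by assay number. Because no cell is tied to an animal, each group counted as 1 sample, and the differences below have no replicate check and no test. Errors are SDs over cells.

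Hepatocytes had values for more of the panel at 24 h than at 0 h on both diets, and at 0 h the ethanol-fed cells had values for more of it than the control cells. The median number of assays with a value per cell was 54 of 84 in control cells at 0 h (quartiles 46 and 62) and 64 in ethanol cells at 0 h (quartiles 51.5 and 69). At 24 h it was 71 on the control diet (quartiles 63.5 and 75) and 71 on the ethanol diet (quartiles 63.25 and 76). The mean was 54.0 ± 10.3 (SD, n = 69 cells) in control cells at 0 h, 67.8 ± 10.4 (SD, n = 55 cells) in control cells at 24 h, 60.4 ± 12.4 (SD, n = 55 cells) in ethanol cells at 0 h and 68.3 ± 11.4 (SD, n = 54 cells) in ethanol cells at 24 h. The common-assay Ct differed in the same order as these numbers: the median over cells of the common-assay median Ct was 14.5 in control cells at 0 h, 13.3 in control cells at 24 h, 13.6 in ethanol cells at 0 h and 13.1 in ethanol cells at 24 h. These medians count a NULL as Ct 30. The means lay closer at 0 h, at 14.3 ± 1.53 (SD, n = 69 cells) in control and 14.1 ± 2.55 (SD, n = 55 cells) in ethanol cells, and fewer control cells at 0 h lay above Ct 17, with 2 of 69 against 6 of 55 control cells at 24 h, 6 of 55 ethanol cells at 0 h and 3 of 54 ethanol cells at 24 h.

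**Figure D1:**
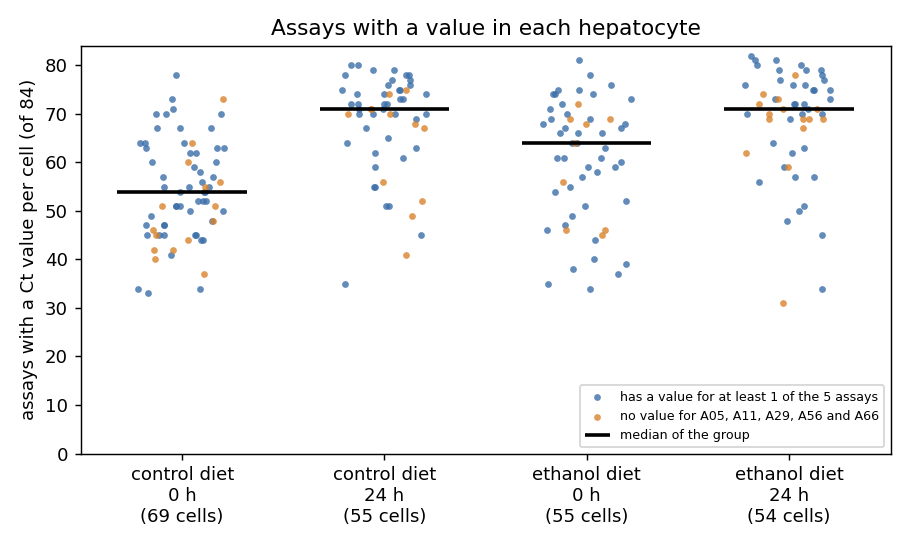
Each point is 1 hepatocyte, the vertical axis is the number of the 84 assays with a Ct value, the black line is the group median, and orange points are the cells without a value for A05, A11, A29, A56 and A66. The medians are 54 and 71 on the control diet and 64 and 71 on the ethanol diet at 0 h and 24 h, and orange points lie among the blue ones in all 4 groups.

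Missing values were not spread evenly over cells. The 5 assays A05, A11, A29, A56 and A66 had no value in the same 51 cells, while among the other 182 cells 5 lacked A05, 0 lacked A11, 18 lacked A29, 39 lacked A56 and 8 lacked A66. Where A05 had a value, its median Ct was 6.20, against a highest Ct of 25.9 in the table. The 51 cells made up 21.7% of control cells at 0 h (15 of 69, exact 95% interval 12.7% to 33.3%), 21.8% of control cells at 24 h (12 of 55, 11.8% to 35.0%), 16.4% of ethanol cells at 0 h (9 of 55, 7.77% to 28.8%) and 27.8% of ethanol cells at 24 h (15 of 54, 16.5% to 41.6%). Differences between groups were therefore also computed within each of these 2 sets of cells. For the other 79 assays, the median number with a value within the 182 cells was 50 in control cells at 0 h, 67 in control cells at 24 h, 58.5 in ethanol cells at 0 h and 68 in ethanol cells at 24 h. Within the 51 cells it was 48, 69, 64 and 69 in the same order.

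**Figure D2:**
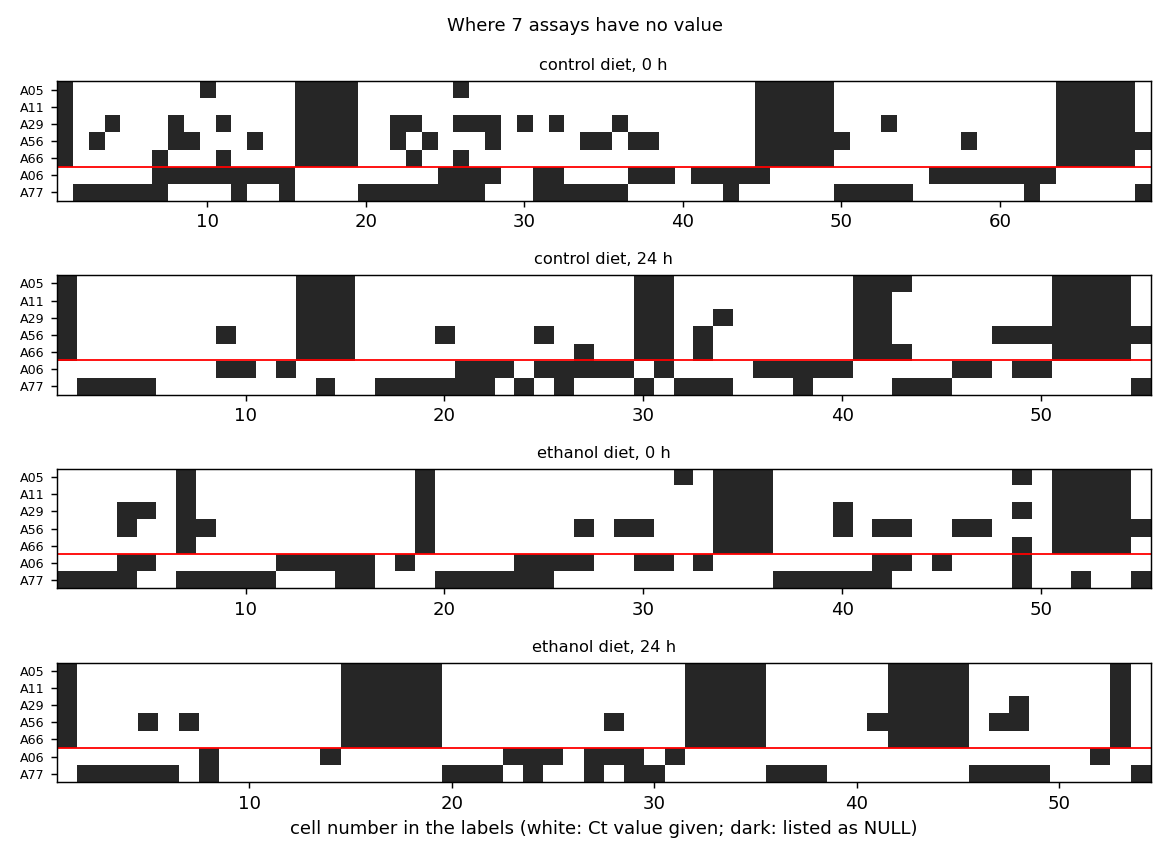
Each panel is 1 group, the horizontal axis is the cell number in the labels, and each row is 1 of 7 assays, dark where the table lists NULL and white where it gives a Ct. A05, A11, A29, A56 and A66 are dark together in 51 cells, mostly in runs of neighbouring cell numbers, and A06 and A77 (below the red line) are dark mainly in other cells.

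On the control diet, the comparison of 24 h with 0 h after resection asked which transcripts differed after partial hepatectomy without ethanol. Of 80 assays compared, 22 had a relative level higher by at least 1 on the log2 scale at 24 h, 3 were lower by at least 1, and 55 differed by less. Together 25 passed the size rule, against up to 10 in simulations of this comparison with no assay changed and cells taken as independent. A59 differed most in the upward direction, by 3.08, from -4.22 ± 2.98 (SD, n = 17 cells) to -1.14 ± 1.97 (SD, n = 38 cells). A82 was higher by 2.88, from -3.08 ± 2.07 (SD, n = 18 cells) to -0.20 ± 2.10 (SD, n = 48 cells). In the other direction, A26 went from -2.04 ± 2.95 (SD, n = 64 cells) to -3.81 ± 3.24 (SD, n = 49 cells), a difference of -1.77, and A65 from 0.03 ± 2.27 (SD, n = 60 cells) to -1.68 ± 1.49 (SD, n = 50 cells), a difference of -1.71. The median difference over the 80 assays was 0.23. Without scaling it was 0.69, so that 32 assays were higher and 2 lower by at least 1. Within the 182 cells that did not lack all 5 assays, 20 of 75 assays compared were higher and 4 lower, and within the 51 cells that lacked all 5, 8 of 42 were higher and 5 lower. A26 differed by -2.05 within the 182 cells and by -0.65 within the 51 cells. With undetected values entered at Ct 30, which adds the share of cells with a value to the level, A59 differed by 7.22, A82 by 10.3 and A65 by -0.92.

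The share of cells with a value differed mostly in the same direction. It was higher at 24 h for 74 of the 84 assays and lower for 9, by at least 20 percentage points for 24 and 0 assays respectively. A08 had a value in 20.3% of control cells at 0 h (14 of 69, exact 95% interval 11.6% to 31.7%) and in 81.8% at 24 h (45 of 55, 69.1% to 90.9%). A82 had a value in 26.1% of cells at 0 h (18 of 69, 16.3% to 38.1%) and in 87.3% at 24 h (48 of 55, 75.5% to 94.7%). Among cells with a value, the relative level of A08 differed by 0.34 between the 2 times, while that of A82 differed by 2.88.

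On the ethanol diet, the comparison of 24 h with 0 h asked which transcripts differed after partial hepatectomy in ethanol-fed animals. It covered 81 assays, of which 10 were higher by at least 1 at 24 h, 3 were lower and 68 differed by less. Together 13 passed the size rule, against up to 11 in simulations of this comparison with no assay changed and cells taken as independent. A53 was higher by 2.14, from -3.23 ± 3.01 (SD, n = 49 cells) to -1.09 ± 2.59 (SD, n = 49 cells). A82 was higher by 2.01, from -3.06 ± 2.68 (SD, n = 31 cells) to -1.05 ± 1.44 (SD, n = 46 cells). A65 was lower, with a difference of -2.22, from 0.60 ± 1.93 (SD, n = 50 cells) to -1.62 ± 2.03 (SD, n = 47 cells), and A44 differed by -1.37, from -0.62 ± 1.36 (SD, n = 41 cells) to -1.99 ± 1.66 (SD, n = 38 cells). With values above Ct 20 treated as missing, a limit chosen after seeing the data, 3 of 80 assays were higher and 6 lower, so the prevailing direction turned, and the difference of A82 was 0.93. With undetected values entered at Ct 30 it was 5.20. Without scaling the difference of A44 was -0.58, and 32 assays were higher and 1 lower by at least 1, around a median of 0.82 against 0.06 with scaling. Within the 182 cells not lacking all 5 assays, 9 of 79 assays were higher and 3 lower. The 9 ethanol cells at 0 h that lacked all 5 assays were too few for a value within that set.

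Shares of cells with a value were higher at 24 h for 65 assays and lower for 17, by at least 20 points for 15 and 0 assays. A17 had a value in 20.0% of ethanol cells at 0 h (11 of 55, exact 95% interval 10.4% to 33.0%) and 53.7% at 24 h (29 of 54, 39.6% to 67.4%). A31 had a value in 45.5% (25 of 55, 32.0% to 59.4%) and 77.8% (42 of 54, 64.4% to 88.0%).

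The same assays stood out on both diets to a degree. Of the 77 assays compared on both, 6 were higher by at least 1 at 24 h on both diets, against 2.86 expected for independent lists of 22 and 10, and 1 was lower on both, against 0.117 expected for lists of 3 and 3. A82 was among the 6, and A65 was the 1. The 2 differences had the same sign for 52 assays, and across assays, which are not independent replicates, Pearson's r was 0.50 and Spearman's rho 0.44. These 2 comparisons share no cells. The expected numbers give every assay the same chance to pass the size rule, although SDs over cells differed widely between assays. Both comparisons also share the 28 common assays used for scaling. In both, more assays had a value at 24 h, with medians of 54 and 71 on the control diet and 64 and 71 on the ethanol diet. The overlap and the correlation therefore do not show a shared response by themselves.

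Before regeneration, at 0 h, ethanol and control cells were compared to describe how the diet groups differed without time after resection. An effect of diet cannot be told apart here from differences between animals. Control cells at 0 h also had more entries listed as NULL, 35.7% against 28.1% in ethanol cells at 0 h. Of 77 assays, 13 were higher by at least 1 in ethanol cells, 3 were lower and 61 differed by less. Together 16 passed the size rule, against up to 9 in simulations of this comparison with no assay changed and cells taken as independent. A26 had the largest difference, -3.05, with -2.04 ± 2.95 (SD, n = 64 cells) in control and -5.09 ± 3.39 (SD, n = 46 cells) in ethanol cells. A58 differed by -1.29, from -4.16 ± 3.09 (SD, n = 52 cells) to -5.45 ± 3.15 (SD, n = 41 cells). A04 was higher by 2.03, from -2.24 ± 2.78 (SD, n = 68 cells) to -0.21 ± 2.35 (SD, n = 55 cells). A21 was higher by 1.99, from -3.20 ± 3.56 (SD, n = 13 cells) to -1.20 ± 1.64 (SD, n = 22 cells), or by 1.02 when medians over cells were compared. The difference of A21 was 3.14 without scaling and 3.77 with undetected values entered at Ct 30. Too few cells had a value for A21 to compare it within the 182 cells or at the limit of Ct 20. Without scaling, 21 assays were higher and 1 lower, around a median of 0.50 against 0.10 with scaling. Within the 182 cells not lacking all 5 assays, 11 of 75 were higher and 1 lower, with A26 at -2.90, A04 at 2.79 and A58 at -0.80, below the size rule. A58 was also below it without scaling, at -0.80, and with undetected values entered at Ct 30, at -0.92, and it was higher by 3.18 in the 51 cells than in the 182 after group means were removed. The imbalance of 13 higher and 3 lower was not kept by every alternative: it was 8 and 7 with medians over cells, 13 and 9 without cells above a common-assay median of Ct 17, and 10 and 6 with values above Ct 20 treated as missing. No value could be had within the 51 cells, of which 9 were ethanol cells at 0 h.

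Shares of cells with a value were higher in ethanol cells at 0 h for 58 assays and lower for 25, by at least 20 points for 13 and 0 assays. A03 had a value in 34.8% of control cells (24 of 69, exact 95% interval 23.7% to 47.2%) and 78.2% of ethanol cells (43 of 55, 65.0% to 88.2%). A83 had a value in 24.6% (17 of 69, 15.1% to 36.5%) and 58.2% (32 of 55, 44.1% to 71.3%).

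At 24 h after resection, ethanol and control cells differed in fewer assays. Of 84 assays compared, 0 were higher by at least 1 in ethanol cells, 5 were lower and 79 differed by less, around a median of -0.03. In simulations of this comparison with no assay changed, up to 11 assays passed the same rule. A76 differed by -1.66, from -6.45 ± 2.59 (SD, n = 20 cells) in control to -8.12 ± 2.67 (SD, n = 22 cells) in ethanol cells, and A77 by -1.52, from -0.28 ± 3.05 (SD, n = 33 cells) to -1.80 ± 3.65 (SD, n = 33 cells). A77 differed by -0.79 within the 182 cells not lacking all 5 assays, by -2.42 within the 51 cells that lacked all 5, by -0.53 when medians were compared and by -0.69 without scaling. A76 differed by -2.73 within the 182 cells. With undetected values entered at Ct 30, A76 differed by -0.78 and A77 by -0.82, both below the size rule. Within the 182 cells, 0 of 82 assays were higher and 5 lower, and within the 51 cells 1 of 52 was higher and 10 lower. Without scaling, 12 assays were higher and 1 lower, around a median of 0.56, so that the direction of the differences at 24 h depended on whether cells were scaled. The share of cells with a value was higher in ethanol cells for 36 assays and lower for 46, and 1 differed by at least 20 points: A18 had a value in 36.4% of control cells (20 of 55, exact 95% interval 23.8% to 50.4%) and 57.4% of ethanol cells (31 of 54, 43.2% to 70.8%).

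**Figure D3:**
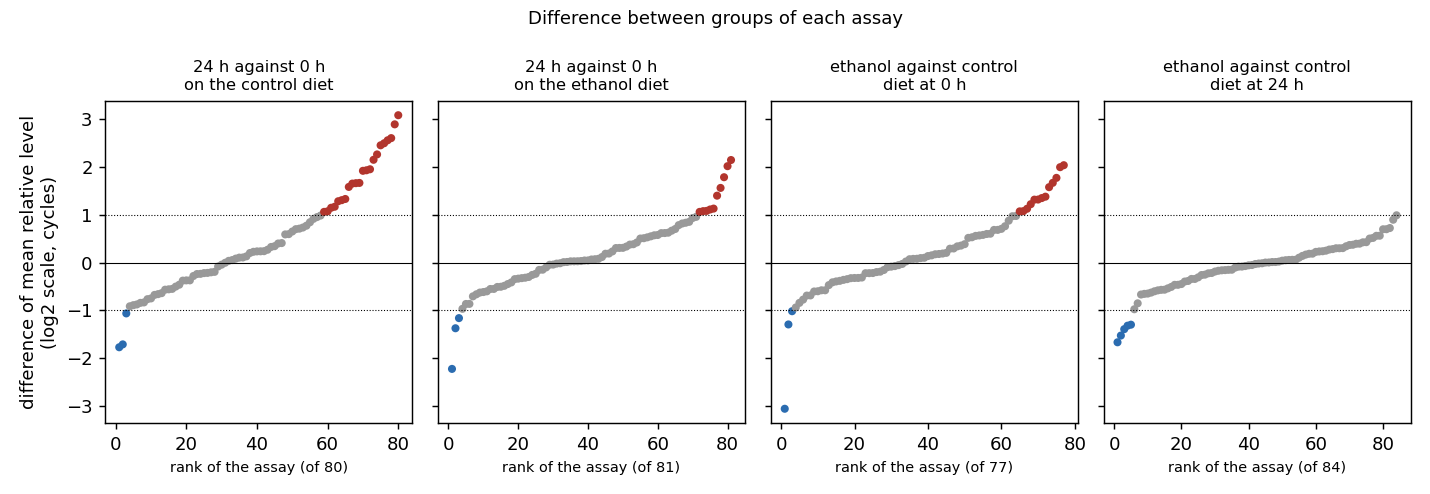
Each panel is 1 comparison, each point is 1 assay ranked by its difference of mean relative level (vertical axis, log2 scale), and red and blue points lie at or beyond 1 and -1 (dotted lines). Assays at or above 1 number 22 and 10 for 24 h against 0 h on the control and ethanol diets, 13 for ethanol against control at 0 h and 0 at 24 h.

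Whether the difference after hepatectomy depended on the diet was described by subtracting the 24 h minus 0 h difference of the control diet from that of the ethanol diet. Of 77 assays, 16 were lower by at least 1 in ethanol, 6 were higher and 55 differed by less, with a median of -0.28. Together 22 passed the size rule, against up to 18 in simulations of this comparison with no assay changed and cells taken as independent. The median was 0.06 with medians over cells, and -0.05 both without scaling and with scaling to every assay the cell has. For A46 the 24 h minus 0 h difference was 2.60 on the control diet and -0.01 on the ethanol diet, which gave -2.61. For A21 the differences were 1.95 and -0.55, which gave -2.50, or -1.48 with medians over cells and -3.36 without scaling. For A26 they were -1.77 and 1.13, which gave 2.89, and for A58 0.08 and 1.56, which gave 1.48. Under the alternatives the value of A58 ranged from 0.69, with undetected values entered at Ct 30, to 2.11, without cells above a common-assay median of Ct 17, and it was 1.06 within the 182 cells. With values above Ct 20 treated as missing, that of A26 was 2.09, from -1.53 and 0.56. At 24 h the diet groups differed by -0.16 for A26 and by 0.18 for A58, against -3.05 and -1.29 at 0 h. For A21 they differed by -0.51 at 24 h against 1.99 at 0 h, and for A46 by -1.30 against 1.32. Between diets, 16 of 77 assays passed the size rule at 0 h and 5 of 84 at 24 h. The 22 assays can therefore largely restate differences at 0 h, where 35.7% of control entries were NULL. They do not by themselves show a response to resection that depends on diet. Without scaling, 8 assays were higher and 13 lower. Within the 182 cells not lacking all 5 assays, 7 of 75 were higher and 19 lower.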

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

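A26 differed in opposite directions after resection on the 2 diets: the 24 h minus 0 h difference was -1.77 on the control diet and 1.13 on the ethanol diet, a difference of 2.89 between diets. It was picked as the 1 assay of 77 that differed by at least 1 in opposite directions. The diet groups differed by -3.05 at 0 h but by only -0.16 at 24 h, so the opposite directions restate the difference at 0 h. SDs over cells were 2.95 to 3.39. The difference of 2.89 between diets was not tested, since each group counted as 1 sample. The signs were opposite under every alternative that gave both values, but the sizes varied. The ethanol value was 0.98 (control -2.05, difference 3.02) among the 182 cells not lacking all 5 jointly missing assays, 0.82 (control -2.04, difference 2.85) with undetected values entered at Ct 30, and 0.56 (control -1.53, difference 2.09) with values above Ct 20 treated as missing. With medians over cells it was 1.00 (control -2.54, difference 3.54). Without scaling the ethanol value was larger, 1.72 (control -1.20, difference 2.92). Within the 51 cells lacking all 5 the control value was -0.65, and the ethanol value could not be had. The 182 and 51 cells and the limit of Ct 20 were chosen after seeing the data.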

How the results depend on the processing

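The limit of Ct 20, the splits by the 5 jointly missing assays and the removal of cells above Ct 17 were chosen after seeing the data. No paired analysis was possible because the cell numbers in the labels name single cells within a group and tie no cell to an animal or to a cell of another group. Entering undetected values at Ct 30 moved every count of assays past the size rule: to 59 from 25 for 24 h against 0 h on the control diet, to 50 from 13 on the ethanol diet, to 51 from 16 for ethanol against control at 0 h, to 28 from 5 at 24 h, and to 55 from 22 for the difference between diets. By its construction this setting adds the shares of cells with a value to the differences of level. Without scaling the count was 33 instead of 13 for 24 h against 0 h on the ethanol diet and 13 instead of 5 for ethanol against control at 24 h; the cause was not tested. Within the 51 cells lacking all 5 assays it was 13 of 42 for 24 h against 0 h on the control diet and 11 of 52 for ethanol against control at 24 h, with fewer assays and cells compared, and the other 3 comparisons had fewer than 10 cells in a group. The other alternatives left the 5 counts within 1.5 times the values reported. Leaving out the 17 cells with a common-assay median above Ct 17 gave 24 higher and 6 lower for 24 h against 0 h on the control diet, 13 and 9 for ethanol against control at 0 h, and 13 and 20 for the difference between diets. With values above Ct 20 treated as missing, 24 h against 0 h on the ethanol diet gave 3 higher and 6 lower instead of 10 and 3. With medians over cells the splits were 16 and 6 for 24 h against 0 h on the control diet, 8 and 7 for ethanol against control at 0 h, and 8 and 12 for the difference between diets; the causes were not tested. The limit of Ct 25 removed 8 values and tests little. The median numbers of assays per cell moved by less than their SD under every alternative run. Of 205 single-assay values under alternatives, 173 moved by at most 0.585 on the log2 scale or, for shares, by at most what their interval allows, 32 moved by more and 0 changed sign. Some of these could not move: keeping only assays with a value in most cells leaves an assay's own value unchanged. The limit of Ct 25 also left every named difference of level as it was. The assays were picked as the largest differences in the same cells, so the lack of sign changes says little about stability. Scaling to reference genes and gene list summaries were not run, as no gene names were at hand. Missing values limit statements most in the control cells at 0 h, where 35.7% of entries were NULL against 18.7% in ethanol cells at 24 h.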

Other observations

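The 3 tests on the 5 jointly missing assays, the repeated draws and the resampling of cells were chosen after results were seen. The other tests below were written before their own results were seen, although the patterns they address came from these data, and the test on less template was added after the first 2 correlations were known. No p-value was computed.

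The lack of A05, A11, A29, A56 and A66 in the same 51 cells may be a mark of an array or reagent batch. Too little template in those cells is argued against: the median number of the other 79 assays with a value was higher in them by 4, at 64 against 60, although their common-assay Ct was slightly higher, with a median of 13.7 against 13.5. Diet and hepatectomy as the whole cause are argued against as well, since the cells with neither, control cells at 0 h, lacked all 5 assays in 21.7%, and the shares ranged over 11.4 percentage points, from 16.4% to 27.8%, with overlapping intervals. Of 229 pairs of cells with neighbouring numbers in a group, 85.6% were alike in lacking all 5 assays or not, against a median of 65.5% and at most 72.9% in 1000 shuffles. A difference between animals or between places in the liver would also give such runs and remains open, because the labels name neither.

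A06 and A77 were also often missing: among the 182 cells, 70 lacked A77 alone, 54 lacked A06 alone, 25 lacked both and 33 had both. In the 51 cells, 49 had a value for A06 and 47 for A77. Between the 51 cells and the rest, after removing group means, A58 was higher by 3.18 and A68 by 2.72 in the 51 cells, and 3 of 79 assays were apart by at least 2.

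The larger number of assays with a value at 24 h than at 0 h on the control diet may come from more template per cell or from transcripts turned on after resection. The next comparison kept cells with a common-assay median between Ct 13 and 15 (23 cells at 24 h and 32 at 0 h). Among them the median number of the 56 assays outside the common set differed by 14, against 17 over all cells. This was above the 8.5 set in advance, with a lower bound of 9.24 over 100 resamples that took cells as independent. Cells outside the window thus do not account for the whole difference. Template may still differ inside the window: over all cells the median common-assay Ct was 14.5 at 0 h and 13.3 at 24 h. The Ct within the window was not compared, so the test cannot decide on template amount. The smaller of the differences within the 182 and the 51 cells was 17, against 17 pooled, but its lower bound over resampled cells, 6.24, was below 8.5, the value set in advance for the difference itself. The 51 cells made up 21.7% of control cells at 0 h and 21.8% at 24 h, so the difference among these cells did not come from unequal shares of them. Template amount, differences between animals, and a different rate of failed reactions between the groups remain open.

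A hypothesis, not established here, is that ethanol cells at 0 h lie partly in the direction of control cells at 24 h. Across 77 assays, the differences of these 2 groups from control cells at 0 h correlated with r = 0.63, against 0.44 simulated for unchanged groups that share control cells, with a covariance of 0.569 against 0.129 simulated. With the control cells split so that the 2 differences shared none, the mean r over 100 splits was 0.49, against 0.52 among the 182 cells not lacking all 5 assays and 0.43 among cells with a common-assay median between Ct 13 and 15. These splits left a median of 68, 64 and 53 assays, so the values of r are over different sets of assays. Splitting does not remove a bias from averaging only the cells with a value. Of entries, 35.7% were NULL in control cells at 0 h, 28.1% in ethanol cells at 0 h and 19.3% in control cells at 24 h. Both differences also share the 28 common assays used for scaling, and SDs over cells differed widely between assays. The correlation therefore does not show a shared direction by itself. An explanation was to be excluded if the lowest r of 100 splits lay above 0.2; this held in the first draw (0.28, 0.32 and 0.21), but in 20 further draws it held in 16, 19 and 12, with lowest values of 0.14, 0.19 and 0.15. With no control cell shared, the mean r over the 20 draws was still 0.47 to 0.50. This argues against shared control cells as the whole cause, although the rule set in advance was not met in every draw. They may add to the unsplit r of 0.63. That split of the cells and less template in control cells at 0 h may each contribute. A control group whose animals differed from the rest also remains open.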
